A study of Mus musculus with 2 samples.

How the data were processed

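Gene expression was measured on 2 two-colour Agilent mouse arrays of one 60-base oligonucleotide design, 1 for each Cre system. Per the labels, amplified RNA from sorted cells was labelled by the Kreatech ULS method, with wild type in Cy3 and Bcl11b-deficient in Cy5 on both arrays, so there was no dye swap. Per the file headers, the images were read by Agilent Feature Extraction 10.5.1.1 for the Cd4Cre array and 10.7.3.1 for the Foxp3Cre array, while the submitters' processing notes name version 10.5.1. The authors deposited for each spot the mean intensity and the local background intensity in each channel, the scanner software's log10 ratio of red over green with its error, its p-value from the software's error model for a single array, and flags. Per the file headers, the software's own ratio was background-subtracted, spatially detrended and dye-normalized. The authors' deposited value table equalled this log10 ratio (largest difference 0), so it adds no second processing; its scale and direction follow from that match. The ratio was set to 0 at 12768 and 13616 gene-probe spots too dim to measure. The median deposited log10 ratio was 0 on each array.

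From the deposited intensities, the background was corrected with normexp (offset 50) on mean signal and median background, and log2 ratios were normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers in either channel (137 and 155) were left out and spots of a probe were averaged. Probes were named through their accession or symbol by a RefSeq table of the GRCm38.p6 assembly, used for names only: 24844 of 41174 probes matched by accession, 5960 by symbol and 1774 by synonym, and 8449 kept the name in the file. Probe coordinates are those of the files, on mm9. A gene was read from its brightest probe over both arrays, and counted as detected where that probe was well above background in at least 1 channel of the array. Where only 1 channel was above background, the brighter channel was set against the higher of the dim channel's own signal and the lowest signal well above background in that channel, per channel after loess and Aquantile normalization, and the result is given as a bound, open to dye bias.

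With 1 array per Cre system, genes were counted at 2-fold on each array with no test. The limma fit tested the mean ratio of both arrays against 0 (intercept only, Benjamini-Hochberg adjustment), so that the difference between Cre systems counts as spread. On simulated ratios for the 14371 genes of this fit (20 draws, 200 changed genes each), it recovered a median of 3% of genes changed 2-fold, 73% of those changed 4-fold and 100% of those changed 8-fold. The median share of false calls was 10.1% (from 1.92% to 30.5% over the draws), above the nominal level, and the prior degrees of freedom were estimated at a median of 9.31 against the 7.07 simulated; the cause was not tested. Calls of this fit are weaker evidence than their adjusted p states. In the simulation each changed gene had the same true change on both arrays. In the real fit Retnla, with a mean log2 ratio of 3.02, was not called, so the simulated recovery does not carry over to it. A lack of calls therefore does not mean that no gene changed 8-fold. Gene lists were described by the median of detected members and its percentile among 10000 random lists of the same size matched in 20 intensity bins. On simulated lists of 20 genes, 0 of 50 unchanged lists, 28 of 50 lists shifted by 0.5 (log2) and 49 of 50 lists shifted by 1 lay above the central 95% of random lists. In the simulation and in the random lists, genes were drawn independently, while members of a real list may vary together. The simulation does not cover this, so a percentile describes where a list lay and is no significance level.

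The gene lists, apart from the second granulocyte and salivary gland panels, were fixed before the data were examined, and members without a probe were left out. The ribosomal list follows its fixed rule, every symbol starting with Rpl or Rps and a digit, so it also holds S6 kinases and pseudogenes; without them the medians were 0.47 and 0.77. The text names Bcl11b, Foxp3, Il10 and Gata3, the 10 highest and 10 lowest genes of each array, the 12 most extreme genes of the same sign on both, members of each list with the largest mean or at least 2-fold, genes that differ most between the arrays, and genes with a bound of at least 2-fold. Some genes that this rule selects are counted in the lists and totals but not reported here by name. The Y-linked genes, Xist and Prb1 were chosen after their values were seen. The alternatives tried were no background subtraction, offset 10, the scanner software's ratio, median centring, the deposited value table, the mean over a gene's probes, no filter and a stricter filter on dim probes, the software's p-value as a further condition, an intensity trend in limma, keeping marked spots, and, chosen after seeing the data, removal of the trend on probe GC content. Values were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. No annotation of the mm9 build was used, so probes are not placed in exons.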

Results

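The series compared regulatory T cells (Tregs, CD4 T cells that restrain immune responses and carry the transcription factor Foxp3) lacking Bcl11b with wild-type Tregs from C57BL/6 mice. Bcl11b is a zinc finger transcription factor of the T cell lineage. Deletion was driven by 2 Cre recombinases: Cd4Cre, which acts in developing T cells before Foxp3 appears, and Foxp3Cre, which acts in cells that already express Foxp3. Each Cre system was measured on 1 two-colour Agilent mouse array, with wild-type RNA in Cy3 and deficient RNA in Cy5 on both. The wild-type pools came from 3 mice each. The labels describe the cells of the first array as sorted for a Foxp3-GFP reporter, which the design text gives for the Cd4Cre mice, and this array is called the Cd4Cre array; the other is called the Foxp3Cre array. All values are log2 ratios of deficient over wild type, so a negative value means lower in the deficient pool.

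Each array held 43379 gene-probe spots of 41174 distinct probes. On the Cd4Cre array 24439 spots were well above background in the wild-type channel and 21773 in the deficient channel. On the Foxp3Cre array these numbers were 23446 and 20689. No spot was saturated. The median SD of the log2 ratio between repeated spots of 1 probe was 0.057 on the Cd4Cre array and 0.070 on the Foxp3Cre array (225 probes each), which covers technical spotting error only. With 1 array per Cre system, the difference on either array has no replicate check and carries no p-value, and dye bias runs in the same direction on both.

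Bcl11b itself was lower in both deficient pools. Its brighter probe, at chromosome 12 from 109153847 to 109153906 (mm9), read -2.46 on the Cd4Cre array (5.50-fold lower) and -1.82 on the Foxp3Cre array (3.52-fold lower), with Feature Extraction errors of 0.30 and 0.26. Its other probe, at chromosome 12 from 109148932 to 109148991, read -1.19 and -0.32, with errors of 0.23 and 0.21. The labels do not say which part of the gene was deleted, so neither probe can be placed inside or outside it.

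The comparison on the Cd4Cre array asked how Tregs differed when Bcl11b was removed during T cell development. Of 29 detected genes of the Treg signature, 17 were at least 2-fold lower in the deficient pool. Foxp3 read -3.57 (11.9-fold lower), the orphan receptor Gpr83 -4.28 (19.5-fold lower), the inhibitory receptor Ctla4 -3.48 and the interleukin 2 receptor chain Il2ra -2.86. The suppressive cytokine Il10 was at least 14.3-fold lower, because the deficient channel was not well above background there. In the same pool, 17 of 21 cytotoxic genes and 10 of 15 myeloid genes were at least 2-fold higher. Of the myeloid genes, 2 were at least 2-fold lower. The higher genes included granzyme A (Gzma, 6.57) and the calprotectin subunits S100a9 (7.02, 129-fold) and S100a8 (6.86).

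In all, 15870 genes were detected on this array, of which 1808 were at least 2-fold higher and 1682 at least 2-fold lower. The share of higher genes among these was 51.8%, but 68.4% when the ratios were centred on the median without loess and 44.7% with the scanner software's own ratio, so the balance turned with the normalization.

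Of the Treg signature genes, 25 were below 0 and 4 above 0 on the Cd4Cre array, 2 of them at least 2-fold higher. The median of -1.20 lay below all 10000 random lists matched on intensity, and was -0.72 with median centring. Besides Foxp3, Gpr83, Ctla4 and Il2ra, the lower genes included Plagl1 (-3.76), Ecm1 (-3.01), Dusp4 (-2.86), the integrin Itgae (-2.32), the costimulatory receptor Tnfrsf4 (-2.28), and the Ikaros family members Ikzf2 (-1.99) and Ikzf4 (at least 2.58-fold lower). The probes of Plagl1 disagreed, since another probe read -0.19. The 2 higher members were S100a4 (3.26) and S100a6 (1.86), calcium-binding proteins also made by memory T cells and myeloid cells. Among 18 suppressor effector genes, 7 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.21 at the 18.8th percentile, which turned to 0.10 where signal was required in both channels of both arrays. Galectin 1 (Lgals1, 2.87) and the granzyme Gzmb (2.31) were higher, and Itgb8, which helps activate TGF-beta, was lower (-1.86).

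Of 21 detected NK and cytotoxic genes, 17 were at least 2-fold higher on the Cd4Cre array and none at least 2-fold lower, and their median of 2.31 lay above all 10000 random lists. They included the NK receptor genes Klrc2 (4.88), Klrk1 (4.43), Klrd1 (3.78) and Klrc1 (3.36), the granule protein gene Nkg7 (3.94), Cd244a (3.40) and Cd160 (2.95). Granzymes and the Klrc receptors belong to families of related genes. Whether their probes also read other members was not checked, so they are uncertain. Th1 genes had a median of 1.46, above all random lists, with 11 of 16 at least 2-fold higher, among them Tbx21, the T-bet gene (2.45), the chemokines Ccl5 (2.92), Ccl3 (2.62) and Ccl4 (2.26), and Il18rap (2.68). Th17 genes had a median of 0.73 at the 99.91th percentile, with 7 of 16 at least 2-fold higher and 3 at least 2-fold lower: Il22 read 4.13 and Il1r1 2.83, while Il6ra read -2.28. Th2 genes had a median of -0.54 at the 2.65th percentile, with Il4ra at -2.39 and Il4 at 1.47, and Gata3, the Th2 and Treg regulator, read -0.71.

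Cell cycle genes were higher as a group on the Cd4Cre array: all 30 were above 0 and 21 at least 2-fold higher, with a median of 1.62 above all random lists. Rrm2, a ribonucleotide reductase subunit, read 2.79, Birc5 2.67, Top2a 2.57 and Aurkb 2.24. Immediate early genes, which respond within minutes to receptor signals, were lower, with a median of -1.52 below all random lists (-0.59 with median centring) and 12 of 20 at least 2-fold lower. Fos read -3.14, Fosb -3.02, Nr4a1 -2.82 and Dusp1 -2.65, while Ier3 was higher (1.63). Of 14 genes of the IL-2 and STAT5 axis, 8 were at least 2-fold lower, with a median of -1.12 below all random lists (-0.31 with median centring); the kinase Pim1 read -2.39 and Jak3 -1.81. Of 20 T cell receptor signalling genes, 6 were at least 2-fold lower, and the median of -0.79 lay at the 0.07th percentile (-0.18 with median centring), with Cd6 at -1.85, Cd5 at -1.70 and Cd4 at -1.13.

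Markers of other cell types stood beside these groups on the Cd4Cre array. Both CD8 T cell markers were higher, Cd8a by 2.56 and Cd8b1 by 1.19, with a median of 1.88. NK cell markers, most of which are also in the NK and cytotoxic list, had a median of 2.06 (7 detected), above all random lists. Myeloid and dendritic markers had a median of 1.38 at the 99.99th percentile (2.15 with median centring), with Ngp at 4.81, Mpo at 3.67 and Lyz2 at 3.58, but Csf1r, the macrophage growth factor receptor, at -1.50. B cell markers had a median of 0.84 at the 99.94th percentile, with Ms4a1, the CD20 gene, at 2.03. Thymocyte markers had a median of 1.19 (3 detected), erythroid markers 0.72 (5 detected) and platelet markers -0.33 (3 detected). The detected thymocyte markers on both arrays were Cd8a, Cd8b1 and Dntt (0.62 on the Cd4Cre array). Their median is therefore the value of a CD8 T cell marker and adds no separate support.

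The comparison on the Foxp3Cre array asked how Tregs differed when Bcl11b was removed after Foxp3 had appeared. Foxp3 was close to even in the deficient and wild-type pools (-0.20), while Ctla4 read 1.22 (2.34-fold higher), the receptor Klrg1 1.54 and Il10 0.78. Signals also differed between the wild-type pools. Foxp3 had a log2 signal of 10.022 in the Foxp3Cre wild-type pool against 12.504 in the Cd4Cre one, and Ctla4 11.073 against 13.311. S100a9 (14.547 against 10.444), Ms4a1 (14.837 against 12.714) and the signature gene S100a4 (15.976 against 15.124) went the other way. Slide, scan and software differ too, so the share of Tregs in the Foxp3Cre pools stays open. An even Foxp3 ratio alone does not show kept Treg identity. The Treg signature had a median of 0.32 at the 99.60th percentile (0.61 with median centring, 0.15 with the mean over each gene's probes), with 2 of 29 genes at least 2-fold higher and none at least 2-fold lower. The transcription factor genes Satb1 (-1.98), Foxo1 (-1.55) and Bach2 (-1.42) were lower, and so were the cytokine receptor genes Il6ra (-2.31) and Il4ra (-2.04).

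Of 15184 genes detected on this array, 446 were at least 2-fold higher and 1749 at least 2-fold lower. The share of higher genes was 20.3%, but 66.7% with median centring and 36.3% with the scanner software's own ratio, so the balance of higher and lower genes on this array depended on the normalization. Median centring moved the median of all genes by 0.25 here and by 0.12 on the Cd4Cre array.

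The 10 lowest genes of the Foxp3Cre array included the chitinase Chia1 (-4.74), Bpifa2 (-4.58), Dnase1 (-4.47), salivary amylase Amy1 (-3.92), Smr3a (-3.50) and carbonic anhydrase Car6 (-3.20). Pip and Cst10 were at least 6.87-fold and at least 6.26-fold lower. Ikzf1, the Ikaros gene, read -2.95. The highest genes included Xlr3c (3.34), cathepsin E (Ctse, 2.43), cathepsin G (Ctsg, 2.41), the inducible heat shock gene Hspa1a (2.40), S100a8 (2.33), S100a9 (2.25) and the platelet chemokine gene Pf4 (2.51). The mast cell proteases Cpa3 and Mcpt4 were at least 5.40-fold and at least 5.08-fold higher.

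Treg transcription factors had a median of -0.49 at the 1.60th percentile on the Foxp3Cre array (-0.11 with median centring, -0.29 with no filter on dim probes), with 7 of 25 at least 2-fold lower, including Smad3 (-1.58) and Nr4a1 (-1.36); Id2, an inhibitor of helix-loop-helix factors, was higher (1.27). The IL-2 and STAT5 axis had a median of -0.78 at the 0.27th percentile (-0.068 with median centring), with Pim1 at -1.82 and Stat5b at -1.19. Conventional and naive CD4 genes had a median of -0.49 at the 1.04th percentile, with 7 of 19 at least 2-fold lower, but 0.059 with median centring. Immediate early genes had one of -0.57 at the 0.99th percentile, but 0.065 with median centring. T cell receptor signalling genes had a median of -0.39 at the 2.46th percentile, with Vav1 at -1.97 and Cd6 at -1.70, but 0.28 with median centring and -0.82 with the mean over each gene's probes. NuRD complex and partner genes had a median of -0.60 at the 1.65th percentile (-0.29 with median centring), with Mbd3 at -1.69.

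NK and cytotoxic genes were modestly higher on the Foxp3Cre array, with a median of 0.69 above all random lists and 21 of 23 above 0; Cd244a read 1.04, while Eomes read -0.42. Th1 genes had a median of 0.13 at the 80.3th percentile (0.81 with median centring), with Tbx21 at -0.57, and Th17 genes one of 0.32 at the 97.6th (0.15 with the GC trend removed, 0.14 with signal in both channels of both arrays), with Il22 at 1.81. Th2 genes had a median of 0.10 at the 75.8th percentile, which turned to -0.019 with the GC trend removed, with Il1rl1, the IL-33 receptor gene (1.49), Il4 (1.46) and Ccr3 (1.43) higher. Gata3 read -0.60. Interferon-stimulated genes had a median of -0.34 at the 7.79th percentile, with 5 of 22 at least 2-fold lower, among them Irf7 (-1.89) and Oas2 (-1.64); median centring turned this median to 0.33. Cell cycle genes had a median of 0.34 at the 99.86th percentile (0.92 with median centring), with Ccne2 at 1.61 and Mcm2 at -1.31. Suppressor effector genes had a median of 0.36 at the 97.7th percentile (0.71 with median centring).

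Among markers of other cell types on the Foxp3Cre array, NK cell markers had a median of 0.70 at the 99.97th percentile, myeloid and dendritic markers 0.52 at the 99.85th, CD8 T cell markers 0.05, thymocyte markers 0.08 (3 detected), erythroid markers 0.56 and platelet markers 1.21 (2 detected). B cell markers had a median of -0.15 at the 26.8th percentile, which median centring turned to 0.41.

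**Figure D1:**
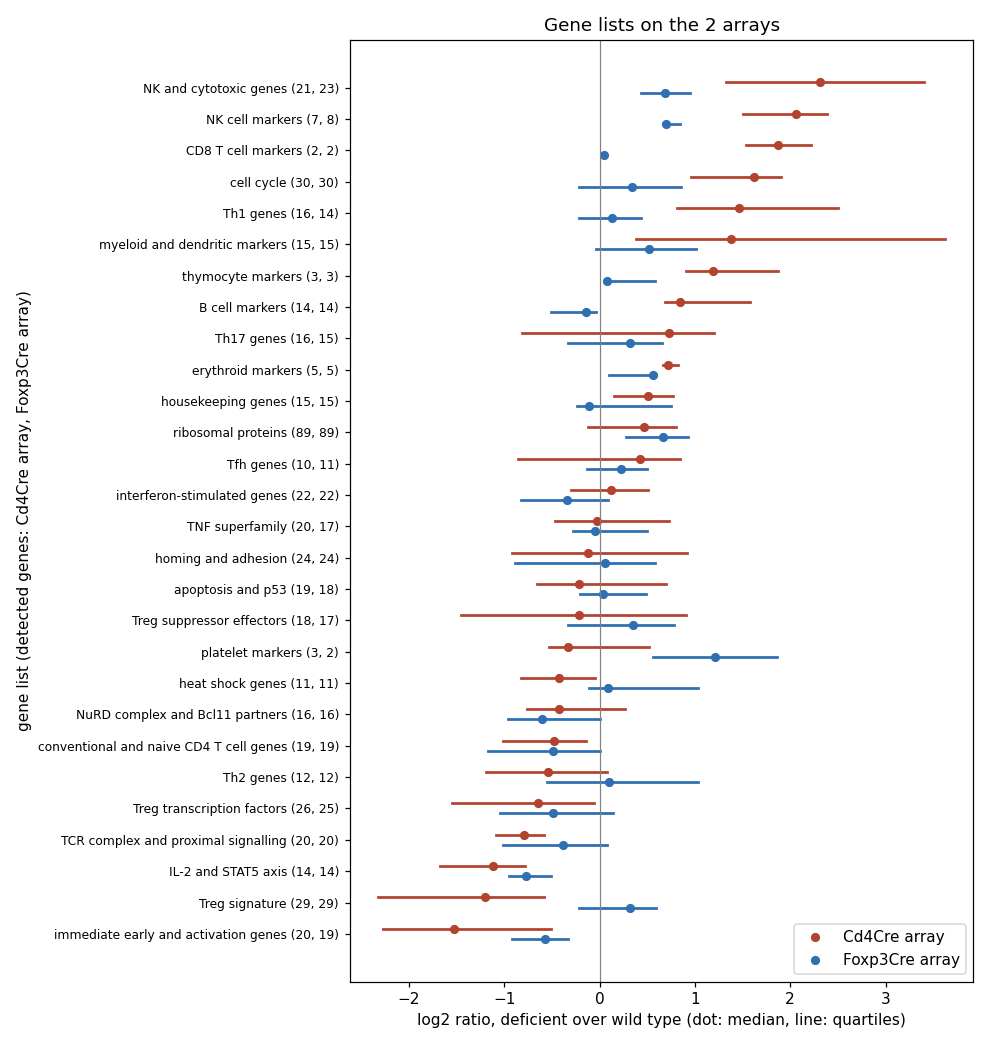
Median (dot) and quartiles (line) of the log2 ratio, deficient over wild type, for each gene list on the Cd4Cre and Foxp3Cre arrays, with the number of detected genes in brackets. The Treg signature sits at -1.20 on the Cd4Cre array and 0.32 on the Foxp3Cre array, and NK and cytotoxic genes at 2.31 and 0.69. Each array's ratios are relative to its own wild-type pool.

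Set side by side, the arrays shared lower values of the following genes, named by size or list membership. Il6ra read -2.28 on the Cd4Cre array and -2.31 on the Foxp3Cre array, Il4ra -2.39 and -2.04, the Janus kinase Tyk2 -1.95 and -2.02, Ikzf1 -1.89 and -2.95, Il6st, the shared IL-6 signalling chain, -1.46 and -1.41, Foxp1 -1.48 and -1.28, and the cohesin gene Rec8 -3.76 and -2.29. Dock8 (-2.13 and -2.57) and Kmt2c (-2.08 and -2.42) were among the 12 lowest, but their probes disagreed: the highest probe of Dock8 read 0.37 and 0.00, and that of Kmt2c 0.71 and -0.42. Tcra (-2.67 and -2.42) belongs to the T cell receptor loci, whose probes are uncertain.

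Among genes higher on both arrays, Retnla was at least 6.19-fold and at least 7.28-fold higher. Its other probe read 2.15 and 2.68, under these bounds (2.63 and 2.86 in log2). Camp was at least 64.4-fold higher on the Cd4Cre array and 2.14 on the Foxp3Cre array, and Lcn2 at least 4.73-fold higher and 1.94. Chil3, of the near-identical chitinase-like genes, read 5.82 and 1.88. Also higher on both were Il22 (4.13 and 1.81), Il4 (1.47 and 1.46), Id2 (1.87 and 1.27), and the receptors Ccr2 (1.37 and 1.17) and Gpr15 (1.52 and 1.29), the last a colon homing receptor.

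Of 14371 genes detected on both arrays, 193 were at least 2-fold higher on both, where independent lists would share 49.5. At least 2-fold lower on both were 656, where independent lists would share 189.7. The balance turned with the scaling, with 1088 higher and 329 lower under median centring and 444 and 888 under the scanner software's ratio. The log2 ratios correlated across genes (Pearson r = 0.476, Spearman rho = 0.496), and 68.1% of the genes had the same sign; genes are not independent replicates. The limma fit of the mean ratio over both arrays, with 1 residual degree of freedom, called 0 genes at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 it held 3251 genes, and the lowest adjusted p was 0.0966, shared by Il6ra, Il4ra and Rec8 among others. Bcl11b had a mean of -2.14 with a standard error of 0.35 (limma adjusted p = 0.101). Median centring gave 311 calls, and requiring signal in both channels of both arrays gave 39.

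**Figure D2:**
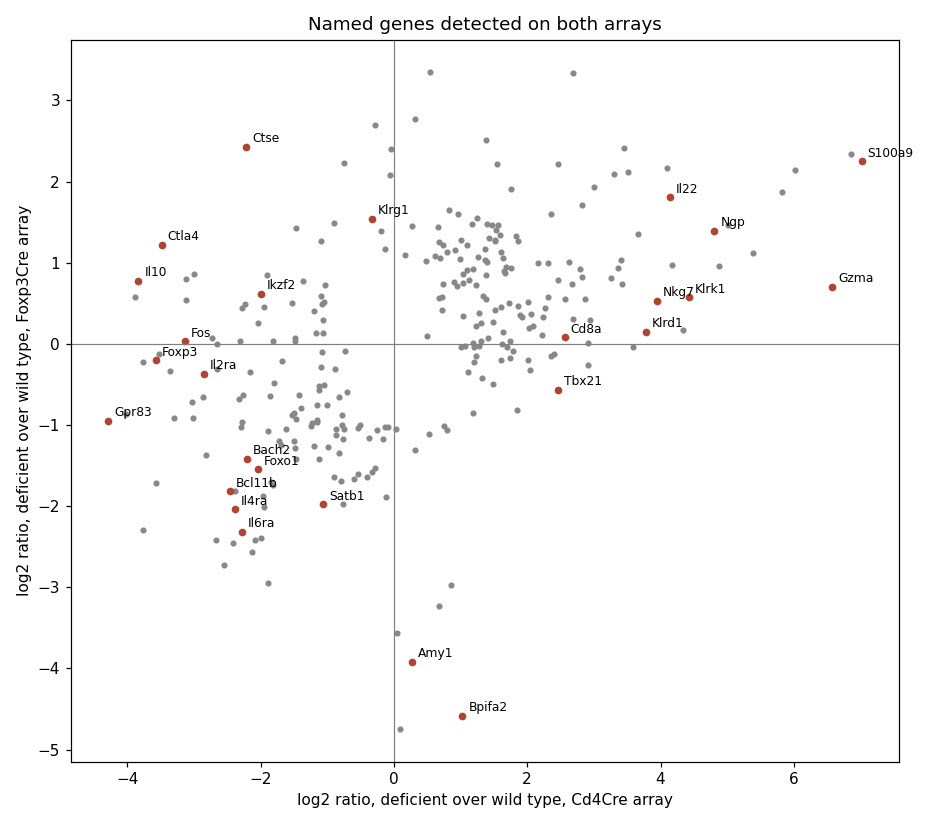
Log2 ratio, deficient over wild type, on the Cd4Cre array (horizontal axis) and the Foxp3Cre array (vertical axis) for the named genes detected on both arrays, each point a gene and red points labelled. Il6ra and Il4ra lie low on both axes, Foxp3 lies at -3.57 on the Cd4Cre axis and -0.20 on the other, Bpifa2 and Amy1 lie low on the Foxp3Cre axis, and genes with 1 channel not well above background, such as Il10, are drawn at their measured ratio although only a bound holds.

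Further gene lists had these medians. On the Cd4Cre array, Treg transcription factors had a median of -0.65 at the 0.09th percentile, conventional and naive CD4 genes -0.48 at the 2.51th, NuRD complex and partner genes -0.43 at the 6.05th, heat shock genes -0.42 at the 7.73th, apoptosis and p53 genes -0.21, homing and adhesion genes -0.12, TNF superfamily genes -0.02, interferon-stimulated genes 0.12, Tfh genes 0.42 and housekeeping genes 0.51. On the Foxp3Cre array, homing and adhesion genes had a median of 0.05, Tfh genes 0.23, TNF superfamily genes -0.05, apoptosis and p53 genes 0.04, heat shock genes 0.09 and housekeeping genes -0.11. Median centring turned the sign for the naive CD4, heat shock, apoptosis, homing and TNF superfamily lists on the Cd4Cre array and for the TNF superfamily (0.46) and housekeeping (0.98) lists on the Foxp3Cre array, and brought the NuRD list on the Cd4Cre array to 0.00. The scanner software's ratio turned the homing list on the Foxp3Cre array to -0.04 and the TNF superfamily list there to 0.05. Other medians that median centring moved by more than 1.5 times were, on the Cd4Cre array, Treg transcription factors (-0.27), Th2 genes (-0.34), suppressor effectors (-0.14), Tfh genes (0.90), interferon-stimulated genes (0.34), housekeeping genes (1.39) and thymocyte markers (2.07). On the Foxp3Cre array they were homing genes (0.50), Tfh genes (0.43), apoptosis and p53 genes (0.51), heat shock genes (1.31), and myeloid (0.81), CD8 T cell (0.78), erythroid (1.18) and thymocyte markers (1.11). The scanner software's ratio moved platelet markers to -1.58 and naive CD4 genes to -0.73 on the Cd4Cre array and Th2 genes to 0.22 and erythroid markers to 0.35 on the Foxp3Cre array. With no filter on dim probes, thymocyte markers on the Cd4Cre array came to 0.38 and platelet markers on the Foxp3Cre array to 0.24. The Th17 median on the Cd4Cre array was 0.46 with signal in both channels of both arrays, and the NuRD median there -0.21 with the mean over each gene's probes. Medians close to 0 also turned: with the mean over probes, housekeeping genes (0.024) and CD8 T cell markers (-0.027) on the Foxp3Cre array, and with the GC trend removed, homing genes on the Foxp3Cre array (-0.09) and TNF superfamily genes on the Cd4Cre array (0.04). Further named genes had another probe closer to 0 than the one given, of which examples follow. On the Cd4Cre array these read 0.24 for Top2a, 0.22 for Il18rap, -0.31 for Itgb8, 0.95 for Klrc2, 2.11 for Klrk1, 1.47 for Cd244a, 2.47 for Lyz2, -0.97 for Il2ra, -3.11 for Gpr83, -1.53 for Ecm1, -1.41 for Rec8 and -0.78 for Pim1. On the Foxp3Cre array they read -0.085 for Pim1, -0.01 for Il1rl1, 0.20 for Cd244a, 0.41 for Id2, -0.066 for Pip, -2.72 for Chia1, -0.82 for Rec8, -0.53 for Oas2 and -0.55 for Smad3. Other probes of Csf1r (-0.57) and Ikzf4 (-0.85) on the Cd4Cre array and of Foxo1 (-0.70) on the Foxp3Cre array were also closer to 0. Ribosomal protein genes had medians of 0.46 and 0.67, but 1.72 and 2.01 with median centring and 0.21 and 0.44 with the scanner software's ratio, and 0.26 and 0.43 with the mean over probes, with Rpl41 at 1.52 and 1.40 and Rpl4 at -1.25 and -1.01; many have near-identical pseudogenes.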

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

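The tests of the slide, scan and software version, the counts of opposite genes under other scalings and the count of the same genes after removal of the GC trend were chosen after the results were seen; removal of the GC trend was added after the data were seen but before its own result, and the salivary gland test was set before its result.

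Some genes lay on opposite sides of 0 on the 2 arrays: 46 were at least 2-fold higher on the Cd4Cre array and at least 2-fold lower on the Foxp3Cre array, and 18 the reverse, where independent lists would share 205.3 and 45.8. The numbers depended on the scaling, with 77 and 98 under the scanner software's ratio and 24 and 32 under median centring, so the larger direction turned, and the difference between the arrays was not tested, since each Cre system has 1 array. Ctla4 (-3.48 and 1.22), Ctse (-2.22 and 2.43) and Ccr3 (-1.47 and 1.43) were lower and then higher, and Bpifa2 (1.03 and -4.58) the reverse. These genes were named by size or list membership and do not describe either group as a whole. Removing the trend on probe GC content left 82.8% of these genes by number (35 and 18). Of the 64, 49 were the same genes (76.6%, under the bound of 80% set for the number), so GC content stays open for a part. A second panel of salivary gland genes had a median of -0.12 on the Foxp3Cre array (from -0.22 to 0.22 under the alternatives, 9 detected). Of these, 4 were at least 1.5-fold lower: Prb1 (at least 2.76-fold lower), Prh1 (-0.88), Bhlha15 (-0.82) and Lpo (-0.65). Only Prb1 was at least 2-fold lower, and 4 genes were above 0. On the Cd4Cre array the panel had a median of -0.19 (9 detected), with 3 genes at least 2-fold higher and 5 below 0. The panel mixed acinar, duct and general epithelial genes, so its median cannot decide on gland RNA in the wild-type pool of the Foxp3Cre array, which stays open. Gland RNA in the Cd4Cre pools was not tested. 0 of the 2 arrays share a slide, so slide, scan and software version cannot be told apart from the Cre system. Nor can the sex of the mice, since Xist was bright on the Cd4Cre array and not detected on the Foxp3Cre array. The biological difference between the Cre systems stays open and untested.

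Spike-in control spots, not used in the comparisons, showed an offset in the file headers' regression of observed on expected log10 ratios: the intercept was 0.220 on the Cd4Cre array and 0.539 on the Foxp3Cre array, with slopes of 0.912 and 1.01.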

How the results depend on the processing

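Depth was limited by signal over background, and no array could be left out. No paired analysis was possible because each Cre system has 1 array. Counts at 2-fold stayed within 1.5 times except as follows; the cause was not tested. Median centring gave 2855 genes higher on the Cd4Cre array, 2044 higher and 1022 lower on the Foxp3Cre array, 1088 higher and 329 lower on both, a correlation of 0.546, 311 genes called over both arrays, 24 genes higher on the Cd4Cre and lower on the Foxp3Cre array and 32 the reverse, and Bcl11b at -1.78 and -1.12. The scanner software's ratio and the deposited value table, which are the same values, gave 2965 lower on the Cd4Cre array, 1153 higher on the Foxp3Cre array, 444 higher on both, a correlation of 0.442, 77 and 98 genes in these opposite directions, and Bcl11b at -2.38 and -1.67. A normexp offset of 10 gave 28 genes lower on the Cd4Cre array and higher on the Foxp3Cre array; these opposite counts were added after seeing the data. Without a filter on dim probes the correlation was 0.440, and signal in both channels of both arrays gave 39 calls from 12438 genes. Bcl11b was -1.83 and -1.07 as the mean over its probes, and -2.34 and -1.64 with the GC trend removed, an alternative chosen after seeing the data. Of 538 comparisons of list medians, 511 kept their sign, as did 2578 of 2590 comparisons of named genes at least 2-fold. Median centring turned Il2rb (0.22), Satb1 (0.032), Ptprc (0.26), Nfkbia (0.18) and Eef1a1 (0.17) on the Cd4Cre array, and Klf2 (0.25), Selplg (0.068), Cd5 (0.069), Jund (0.26), Junb (0.24) and Rpl4 (0.012) on the Foxp3Cre array, as well as the Foxp3Cre medians of the naive CD4 (0.059), T cell receptor (0.28) and immediate early lists (0.065). Averaging probes turned Rps13 on the Cd4Cre array (-0.068).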

Other observations

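Y-linked genes, chosen after their values were seen, were lower in the deficient pool of the Cd4Cre array: Ddx3y read -3.12, Eif2s3y -2.24 and Kdm5d -2.04, while Xist, the X inactivation transcript, read 0.63, and another of its probes 2.26. A second probe of Ddx3y read -0.04, and Uty was not detected. Xist was bright in both channels there, with log2 signals of 14.67 in the wild-type pool and 15.30 in the deficient pool. On the Foxp3Cre array Ddx3y read 0.54, Eif2s3y 0.49 and Kdm5d 0.26, while Uty was 2.14-fold higher, with another Uty probe at -0.01, and Xist was not detected. The log2 signals of Eif2s3y were 12.43 in the wild-type and 10.19 in the deficient pool of the Cd4Cre array, against 13.98 and 14.47 on the Foxp3Cre array. Xist beside Y-linked signal in the Cd4Cre wild-type pool goes with cells of both sexes. Y-linked signal without Xist on the Foxp3Cre array goes with male cells. The labels do not give the sex of the mice. It cannot be told apart from genotype on the Cd4Cre array or from the Cre system between the arrays.

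In this part, the tests of a lower share of Tregs, of swapped pools and of T cells in place of Tregs were chosen after the results were seen, and removal of the GC trend was added after the data were seen but before its own result. In the deficient pool of the Cd4Cre array, Treg genes were lower while cytotoxic and granulocyte genes were higher. Bcl11b, whose higher probe still read -1.19, argues against a swap of the RNA pools between the dyes only if both pools held similar shares of T cells. T cell receptor genes were also lower in the deficient pool, so this gene alone cannot exclude a swap. GC content is argued against by list medians that kept at least 96.1% of their size once its trend was removed. Granulocytes in the deficient pool are a candidate source of the granulocyte part: a second granulocyte panel, not looked at before, had a median of 2.38 (4.77 with the scanner software's ratio, but 1.76 with no filter on dim probes and 1.83 with no background subtraction, both under the bound of 2 set before) with 10 of 12 detected genes at least 2-fold higher, led by Camp (at least 64.4-fold higher), Chil3 (5.82) and Ltf (5.02), although Csf3r (0.63) and Mmp9 (-0.37) were not and the sort on Foxp3-GFP would remove such cells; the panel's median was also 1.88 on the Foxp3Cre array. Treg-restricted genes had a median of -2.86 (7 detected, from -4.28 to -0.94). Their list was written after the results were seen and holds Foxp3, Gpr83, Ctla4 and Il2ra, so this low median is no independent support. T cell receptor genes, which conventional or cytotoxic T cells would leave near 0, had a median of -0.79 that depended on the scaling (-0.18 with median centring). The same sort is meant to remove cells without Foxp3, but the low Foxp3 transcript leaves its purity open. Conventional or cytotoxic T cells in place of Tregs therefore cannot be told apart from lower Treg genes within Tregs. Nor can a lower share of Tregs with all other types raised alike: the medians of B cell and NK cell markers differed by 1.22 (standard error 0.59), which is 2.06 standard errors and past the bound of 2 written for 1 pair, but within 2.39, the bound raised for the largest of 3 pairs after the value was seen. The granulocyte panel was not among the 3 pairs. Its median of 2.38 (quartiles 1.15 and 4.32) lay above the 0.84 of B cell markers (quartiles 0.69 and 1.58). The ranges between the quartiles overlapped, and this difference was not tested.

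The log2 ratios of the 2 arrays correlated across genes, and both arrays share one dye orientation. Removing the GC trend kept 99.0% of the correlation, which argues against GC content. Read across different, non-overlapping probes of 4511 genes, the correlation was 0.389 against 0.507 with the same probes, so 76.7% was kept (95% range from 73.8% to 79.4%), between the bounds of 50% and 80% set before the test. Within 1 array, the 2 probes of a gene correlated at 0.640 on the Cd4Cre array and 0.637 on the Foxp3Cre array. Any lasting difference between probes of a gene would lower the correlation across probes, so this test cannot single out dye bias. Probe-specific dye bias remains open, and a dye bias shared by all probes of a transcript was not tested. A shared effect of Bcl11b loss stays open as a hypothesis.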
